A study of Homo sapiens
Mus musculus and Mus musculus with 98 samples.

How the data were processed

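RNA was measured in 45 tumours grown in mice from 4 human cancer cell lines, and each tumour was hybridised to 2 arrays, the Illumina Human-6 V2 BeadChip and the Illumina Mouse-6 V1.1 BeadChip. There were 46 human arrays, the 45 tumours and 1 mixture of PC14 cells with normal mouse brain. There were 52 mouse arrays, the 45 tumours, 3 normal brains, 3 mixtures titled PC_BRM and 1 mixture titled BR_PCM. Per the labels, total RNA was isolated with the mirVana kit and was amplified and labelled with biotin by the TotalPrep procedure. The share of each RNA in the mixtures was not given in the sources used here.

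Signals were exported by the authors with the Sample Gene Profile option of BeadStudio, whose version was not given in the sources used here. The deposited raw tables hold 1 intensity per probe and array, in arbitrary units and not logged, with 0 values at or below 0. The deposited normalized tables hold log2 values that the authors had quantile normalized over all arrays of a platform. Recomputing them as the quantile-normalized log2 of the raw tables gave the same values to within 5e-05. The human raw table used here holds 46713 probes, of which 46693 were matched to the deposited log2 values that carry probe identifiers by their values over all human arrays. The mouse raw table holds 46628 probes. No detection p-values or negative control probes were used here.

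The human probes were named from the reference annotation of the probe identifiers. Of these, 22181 had 1 gene symbol, 35 had several and were not named, and 24497 had none. In all, 18703 genes had a probe, and each gene was represented by its probe with the highest mean log2 value over all human arrays. No table that names the mouse probes by gene was used here, so mouse results are given as counts of probes and as 5 classes read from the descriptions inside the probe identifiers. These were 300 immunoglobulin segment probes, 52 T cell receptor segment probes, 11 mitochondrial genome probes, 217 reverse complement probes and 45 bacterial, plant or reporter probes. The planned gene list tests, named genes and neuron level on the mouse array could not be run for the same reason.

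The raw intensities of each platform were background corrected with normexp and an offset of 50, quantile normalized over all arrays of the platform and logged to base 2 in limma 3.58.1 on R 4.3.3. Probes above their array's median on at least 3 arrays were tested, 39823 on the human array and 37352 on the mouse array, which left 17709 human genes with 1 probe each. A linear model with 1 mean per group was fitted over all arrays of a platform with lmFit and eBayes. Contrasts were two-sided, p-values were adjusted by Benjamini-Hochberg over the tested probes, and an adjusted p under 0.05 was called passing. Whether the brain minus skin difference, or the tumour-bearing brain, differed between lines was tested with limma's moderated F. A 2-fold change is a difference of 1 log2. In the mean contrasts each line had the same weight.

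The 30 gene lists of cell types, organs and pathways were written down beforehand and tested with limma's camera at a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation. The members of a list that passed were counted over all tested probes and again adjusted over the list alone. A camera test asks whether a list moved relative to all other genes, so it can call a list whose members do not pass on their own. Named genes followed a rule. For the brain against skin and brain against the third site contrasts these were the 8 genes with the largest rise and the 8 with the largest fall among those that passed with the same sign in every line, and from each list up to 3 passing members with the smallest adjusted p in each direction. For the other contrasts they were the 4 largest in each direction, or the 6 smallest adjusted p for an F test. The text prints a part of these, picked after their values were seen. Other list members are given as values. The contrasts, tests, lists, naming rule and first set of alternatives were chosen before the data were examined.

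Human signal and mouse signal are the mean raw intensity of an array above its own median on the human and on the mouse array. They are given as a percent of the mean of the same line's skin arrays and of the mean of normal brain. The mixture on the human array is 1 array, so it was compared with the mean of PC14Br4 skin without a test, and the median of each list was placed among 10000 random lists of the same size and similar level. The relation between mouse and human measures over the 17 brain tumours was computed on values centred within line, with 100000 permutations within line, two-sided. Because the mouse neuron list could not be named, the mean of the 664 mouse probes at least 3 log2 higher in normal brain than in skin tumours stood in its place. This measure and the log2 ratio of mouse to human signal were chosen after seeing the data.

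The alternatives tried were scaling to the same 75th percentile in place of quantile normalization, the deposited normalized values, no background correction, no filter and a stricter filter, only the groups compared, array weights, the replicate number as a block, leaving out probes that rose on the mixtures, and leaving out each array in turn. Chosen after seeing the data were leaving out the 14 human arrays with under 30% of the human signal of skin, leaving out PC14Br4 lung 2 and PC14Br4 brain 3, leaving out the 3 brain tumours with a mouse signal under 75% of the lowest normal brain, and the third site against skin within each line. The replicate numbers of the human and mouse arrays of a group were checked for pairing between sites. No chip number was read from the labels, so no chip block was fitted. The number of arrays limits the precision.

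The fit was tested on simulated data with 100 probes changed by 1 log2 and 100 by 2 log2. The errors were normal, with the same spread of a probe in every group. The real groups were less alike, with an SD of human signal of 102.8 in KM12M brain and 4.00 in A375SM brain. The rates may thus not hold for the real data. For brain against skin over the 4 lines, 81% of the changes of 1 log2 and 99% of those of 2 log2 were called, with 5 false calls. For the contrasts within 1 line on the human array, 63% to 66% of the changes of 1 log2 were called. In 48 combinations of a measure and a group of 4 or 5 arrays, the array farthest from the others was tested with Dixon's ratio. Figures were drawn with matplotlib 3.10.9 on Python 3.11.15.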

Results

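Cells of 4 human cancer lines were grown as tumours in several organs of mice. The RNA of each tumour sample, human RNA of the cancer cells together with RNA of the mouse tissue around them, was measured on a human array and on a mouse array. KM12M, a colon cancer line, gave 4 brain, 4 skin and 3 cecum tumours. MDA-MB231Br3, a breast cancer line, gave 5 brain, 5 fat pad and 4 skin tumours. PC14Br4, a lung adenocarcinoma line, gave 3 brain, 3 lung and 4 skin tumours, and A375SM, a melanoma line, gave 5 brain and 5 skin tumours. The mouse array also held 3 normal brains and 4 mixtures of PC14 cells with normal mouse brain, and the human array held 1 such mixture. Median raw intensities lay between 71.3 and 97.5 on the human arrays and between 55.8 and 132 on the mouse arrays. The number of arrays limits the precision, and the p-values measure the spread between these tumours only.

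Brain samples carried less human signal than skin samples of the same line in most cases. In A375SM the human signal, the mean raw intensity above the array median, was 46.9 ± 4.00 (SD, n = 5) in brain and 370.6 ± 53.0 (SD, n = 5) in skin, with no overlap between the groups. Brain stood at 12.7% of skin in this line. Single brain tumours ranged from 12.9% to 100.3% of skin in KM12M, from 12.6% to 40.2% in MDA-MB231Br3 and from 12.2% to 95.7% in PC14Br4. The cecum tumours lay between 52.7% and 86.1%, the fat pad tumours between 88.7% and 113%, and the lung tumours between 13.5% and 116%. On the mouse array the signal was 354.7 ± 20.8 (SD, n = 3) in normal brain, 414.2 ± 31.4 (SD, n = 5) in A375SM brain and 90.8 ± 41.9 (SD, n = 5) in A375SM skin. GAPDH, a glycolysis enzyme made by most cells, had a raw intensity of 179.9 ± 110.0 (SD, n = 5) in A375SM brain and 20660 ± 1983 (SD, n = 5) in A375SM skin.

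**Figure D1:**
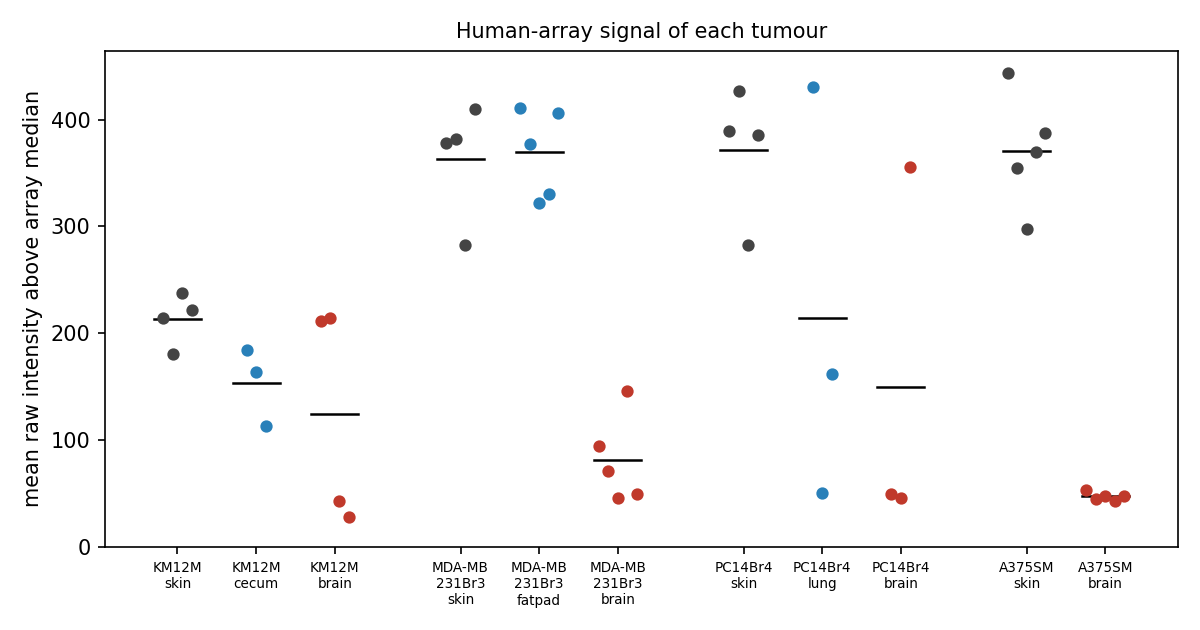
Human-array signal of each tumour, as the mean raw intensity above the array median in arbitrary units. Each point is 1 tumour (grey skin, blue cecum, fat pad or lung, red brain) and each bar is a group mean; the 5 A375SM brain tumours sit between 42.7 and 53.1 and the 5 A375SM skin tumours between 297.5 and 443.7.

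In skin, KM12M and A375SM stood apart in lists of their tissue of origin. The gut epithelium list averaged 8.63 ± 0.17 log2 (SD, n = 4) in KM12M and 6.25 to 6.30 log2 in the other lines. Among its members, LGALS4, a galectin of the intestinal lining, reached 11.55 log2 in KM12M, and CDX1, an intestinal transcription factor, reached 10.96 log2. The melanocyte list averaged 8.37 ± 0.40 log2 (SD, n = 5) in A375SM and 6.22 to 6.62 log2 in the other lines, with SOX10, a neural crest transcription factor, at 10.54 log2. EPCAM, an epithelial adhesion protein, was at 12.60 log2 in KM12M and at 6.31 to 6.92 log2 elsewhere. VIM, an intermediate filament of mesenchymal cells, was at 11.87 log2 in KM12M and at 14.49 to 14.61 log2 elsewhere. The epithelial adhesion list averaged 9.32 log2 in KM12M, 6.94 log2 in MDA-MB231Br3, 6.59 log2 in A375SM and 6.52 log2 in PC14Br4. No test was run on these differences.

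CAMKV, FFAR4 and SNAP25 gave the largest rises on the human array in brain tumours relative to skin tumours of the same lines. This compared whole samples of tumour and mouse tissue, not tumour cells alone. On the single mixture of PC14 cells with normal mouse brain, the same probes were 4.52, 2.57 and 5.22 log2 above PC14Br4 skin. SNAP25, a protein of synaptic vesicle fusion, was 7.06 ± 0.23 log2 higher in brain (SE, 17 brain and 17 skin tumours, adjusted p = 9.01e-23). Its raw intensity in each of the 17 brain tumours, 4268 at the least, exceeded that in every tumour at the other sites, 591.7 at the most. CAMKV, a kinase-like protein of neurons, rose by 7.11 ± 0.28 log2 (adjusted p = 2.74e-20), SNAP91, a clathrin adaptor of synapses, by 6.85 log2, and BSN, a scaffold of the presynaptic active zone, by 6.75 log2. RTN1, NTRK3, CAMTA1 and FFAR4 rose by 6.83, 6.67, 6.66 and 7.06 log2, though the other probe of FFAR4 was at -0.0012 log2. The largest falls were in HSPA1B, a heat shock protein (-3.41 ± 0.48 log2, adjusted p = 2.6e-07), CD44, a hyaluronan receptor (-3.32 log2), RPL14, a ribosomal protein (-3.27 log2), and EIF3A, a translation initiation factor (-3.22 log2). USP49, HAUS2, SLC25A51 and DSTN were at -3.20, -3.19, -3.16 and -3.13 log2.

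In all, 26734 of 39823 probes passed, 14828 higher and 11906 lower in brain, and 13695 genes had a passing probe. At least 2-fold, 3958 probes were higher and 5546 lower. Before normalization the 3958 higher probes differed by a median of 0.018 log2 between brain and skin, with 57% higher in brain and 285 higher by 1 log2 or more, whereas the 5546 lower probes differed by a median of -2.53 log2. With arrays scaled to the same 75th percentile, the median difference of all probes was 0.36 log2, against 0.067 log2 after quantile normalization, and 71.3% of the 37257 passing probes were higher, against 55.5%. Without the 14 arrays with under 30% of the human signal of skin, a choice made after seeing the data, 2928 probes passed.

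The neuron list held 43 measured genes, of which 22 were higher in brain, 13 lower and 8 not passing. Adjusted over the list alone, 36 passed. Its camera test gave an adjusted p = 8.34e-05, which became adjusted p = 0.205 with an estimated correlation. SV2A, a synaptic vesicle glycoprotein, rose by 6.42 log2, whereas ENO2, the neuronal enolase, which the tumour lines also expressed in skin, fell by 2.04 log2, and NRGN and VAMP2 were at -0.95 and -0.51 log2. The raw intensity of ENO2 was 80.5 in A375SM brain and 1868 in A375SM skin. Markers of the other brain cells went both ways. Of 13 measured genes of GABA and glutamate handling, 4 were higher and 5 lower, with GAD1, the enzyme of GABA synthesis, at 6.11 log2 and GLUD1, the mitochondrial glutamate dehydrogenase, at -2.40 log2. Of 16 astrocyte genes, 7 were higher and 5 lower, with SPARCL1 at 5.78 log2 and SLC1A2, a glutamate transporter, at 2.34 log2. Of 13 oligodendrocyte and myelin genes, 5 were higher and 6 lower. MBP, a main protein of myelin, rose by 5.03 log2 while its other probe was at -0.68 log2, MAG rose by 2.15 log2, and OLIG2 fell by 0.81 log2. Of 17 microglia and macrophage genes, 3 were higher and 5 lower, with AIF1 at 2.44 log2 and CD68 at -2.49 log2. Of 16 endothelium genes, 5 were higher and 5 lower, with CLDN5, a tight junction protein of brain vessels, at 2.88 log2 and PECAM1 at 1.2 log2. Human signal fell in the same comparison, as given above for each line.

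Cell division genes were lower in brain on the human array: of 28 measured, 25 fell, 1 rose and 2 did not pass, and 26 passed adjusted over the list alone. CENPF, a centromere protein, was at -2.36 log2 and MCM2, a replication helicase subunit, at -1.95 log2, while PLK1, a mitotic kinase, rose by 2.02 log2. The list's adjusted p = 0.0179 became adjusted p = 0.706 with an estimated correlation. Of 19 oxidative phosphorylation genes, 18 fell and 1 rose, and 19 passed adjusted over the list alone. ATP5F1B, a subunit of the ATP synthase, was at -1.93 log2 and COX6C at -1.64 log2. NDUFV1 was at 1.11 log2, and at -0.82 log2 with scaling to the 75th percentile. This list also had an adjusted p = 0.0179, and an adjusted p = 0.706 with an estimated correlation. Of 16 cholesterol synthesis genes, 14 fell, 1 rose and 1 did not pass, with 15 passing adjusted over the list alone. NSDHL, a sterol dehydrogenase, was at -2.29 log2 and EBP, a sterol isomerase, at -1.92 log2, while SC5D rose by 1.52 log2. The adjusted p = 0.0221 became adjusted p = 0.706 with an estimated correlation. Human signal in the brain samples moved with these falls. Over the tumours that kept at least 30% of the human signal of skin, a choice that itself favours tumours without a fall in strongly expressed genes, the median was -0.12 log2 for the cell cycle list, with 2 genes still lower, -0.18 log2 for cholesterol synthesis and -0.014 log2 for oxidative phosphorylation, with 0 genes lower in each in limma. The sign turned for COX6C (0.047 log2) and NDUFV1 (-0.18 log2), and in other lists for GAPDH (0.051 log2) and OLIG2 (0.057 log2).

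The other lists were not called by camera. Glycolysis had 2 of 10 genes higher and 8 lower, with PGK1 at -2.44 log2 and GAPDH at -2.27 log2. Hypoxia had 2 of 17 higher and 13 lower, with VEGFA, a growth factor of vessels, at 2.00 log2 and ANGPTL4 at -2.75 log2. Interferon response had 1 of 18 higher and 13 lower, with MX1, an antiviral GTPase, at -2.48 log2 and OAS1 at 1.10 log2, whose other probes were at -0.66 and -0.026 log2. NF-kB inflammation had 4 of 17 higher and 9 lower, with NFKBIA at 1.78 log2, CXCL8, a neutrophil chemokine, at -2.87 log2 and SOD2 at 2.34 log2, whose other probe was at -0.056 log2. Antigen presentation had 0 of 13 higher and 8 lower, with HLA-B at -2.49 log2. Unfolded protein and amino acid stress had 1 of 13 higher and 9 lower. Fibroblast and collagen matrix had 0 of 23 higher and 16 lower, with FN1 at -0.99 log2. Mesenchymal genes had 3 of 15 higher and 11 lower, with ZEB1 at 2.41 log2, and epithelial adhesion had 0 of 16 higher and 6 lower, with KRT18, a keratin of simple epithelia, at -2.60 log2. Reactive astrocyte genes had 1 of 13 higher and 8 lower, choroid plexus 2 of 8 higher and 2 lower, and smooth muscle 3 of 10 higher and 7 lower. Skeletal muscle had 2 of 12 higher and 5 lower, adipocyte 2 of 12 higher and 3 lower, and keratinocyte 3 of 12 higher and 4 lower. Lung epithelium had 5 of 14 higher and 0 lower, gut epithelium 3 of 16 higher and 1 lower, and melanocyte 1 of 11 higher and 4 lower. Lymphocyte had 4 of 9 higher and 0 lower, neutrophil 4 of 9 higher and 1 lower, and erythrocyte 2 of 6 higher and 0 lower. The median and the camera direction had opposite signs for the GABA and glutamate, endothelium, choroid plexus, keratinocyte and skeletal muscle lists, and the mean and the direction for the adipocyte, choroid plexus, keratinocyte and microglia lists.

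Relative to the third site of each line (cecum, fat pad or lung), brain tumours had the largest rise in CAMKV, a gene also among the largest rises over skin. CAMKV rose by 6.90 ± 0.35 log2 (SE, 12 brain and 11 third-site tumours, adjusted p = 7.51e-17), SNAP25 by 6.39 ± 0.28 log2 (adjusted p = 3.03e-18) and SLC32A1, the vesicular GABA transporter, by 6.18 log2. RTN1, BSN and SNAP91 rose by 6.52, 6.45 and 6.43 log2, GAD1 by 5.67 log2, and MBP by 4.36 log2 with its other probe at -1.34 log2. The largest falls included SLC25A51 (-2.66 log2), ANXA1, an annexin of inflammation (-2.59 ± 0.39 log2, adjusted p = 1.38e-05), HSPA1B (-2.59 log2) and KRT18 (-2.44 log2). The neuron list had 21 of 43 genes higher and 7 lower, 29 passing adjusted over the list alone, with an adjusted p = 8.03e-08 and an adjusted p = 0.0256 with an estimated correlation. The cell cycle list had 22 of 28 genes lower and 1 higher, with CENPF at -1.81 log2 and MKI67 at -0.59 log2, and 25 passed adjusted over the list alone. Oxidative phosphorylation had 18 of 19 lower, all 19 passing adjusted over the list alone, with UQCRC1 at -1.86 log2 and COX6C at -1.24 log2. Both lists had an adjusted p = 0.00381 and an adjusted p = 0.635 with an estimated correlation. Cholesterol synthesis had 14 of 16 lower, 15 adjusted over the list alone, with HSD17B7 at -2.38 log2 and EBP at -1.29 log2, or 0.028 log2 over the tumours that kept human signal (camera adjusted p = 0.0373). Antigen presentation had 9 of 13 lower, 10 adjusted over the list alone, with HLA-B at -1.99 log2 and HLA-DRA at -0.41 log2 (camera adjusted p = 0.0437). For these lists too it was adjusted p = 0.635 with an estimated correlation. The NF-kB inflammation list had 2 of 17 higher and 5 lower and was not called (adjusted p = 0.55).

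In this comparison 14271 probes passed, 5856 higher and 8415 lower. Before normalization the 2428 probes at least 2-fold higher differed by a median of 0.096 log2, with 79.4% higher in brain. The 3285 probes at least 2-fold lower differed by a median of -1.83 log2. With scaling to the 75th percentile 33875 passed and 72.2% were higher, against 41.0%, with the median of all probes at 0.21 log2 against 0.037 log2. Without the arrays poor in human signal 1340 passed, without PC14Br4 brain 1 it was 7956 and without PC14Br4 lung 1 it was 8943, with array weights 312, and with only the groups compared in the fit 1153.

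Between the third site and skin, 2 matrix metalloproteinase genes passed, both higher at the third site. MMP10, a stromelysin, rose by 0.85 ± 0.15 log2 and MMP7, matrilysin, by 0.37 ± 0.066 log2 (SE, 11 third-site and 12 skin tumours, adjusted p = 0.0373 for both). MMP10 was at 9.76 log2 in cecum and 6.16 log2 in skin of KM12M, at 7.75 log2 in fat pad and 7.99 log2 in skin of MDA-MB231Br3, and at 6.22 log2 in lung and 7.02 log2 in skin of PC14Br4. MMP7 was at 8.71 log2 in cecum and 7.64 log2 in skin of KM12M, at 6.43 log2 in both fat pad and skin of MDA-MB231Br3, and at 6.048 log2 in lung and 6.002 log2 in skin of PC14Br4. Of the 2 probes, 0 had the same sign in every line in limma, and the largest rise of both was in KM12M. In limma, 1652 probes had an unadjusted p under 0.05. The NF-kB inflammation list was higher at the third site (17 genes, median 0.28 log2, 5 passing adjusted over the list alone, adjusted p = 3.16e-11, adjusted p = 0.0215 with an estimated correlation), with CCL20 at 1.12 ± 0.21 log2 (adjusted p = 0.0637). The erythrocyte list was higher too (6 genes, median 0.37 log2, 1 passing adjusted over the list alone, adjusted p = 0.00855, adjusted p = 0.0311 with an estimated correlation). Fitted within KM12M, MDA-MB231Br3 and PC14Br4, a choice made after seeing the data, its medians were -0.0076, 0.022 and 0.13 log2 (adjusted p = 0.289, 0.681 and 0.093). The antigen presentation and lung epithelium lists, with 2 and 1 genes passing adjusted over the list alone, both had an adjusted p = 0.00144, and an adjusted p = 0.163 and 0.0791 with an estimated correlation. The gut epithelium list had an adjusted p = 0.0134, and adjusted p = 0.407 with an estimated correlation, the microglia and macrophage list 0.033, and adjusted p = 0.132 with an estimated correlation. The cell cycle list was lower with an adjusted p = 0.0475, and adjusted p = 0.836 with an estimated correlation. The count of 2 fell to 0 without KM12M skin 1, 3 or 4, KM12M cecum 1, MDA-MB231Br3 fat pad 2, 3 or 5, MDA-MB231Br3 skin 2, 3 or 4, PC14Br4 lung 3 or PC14Br4 skin 3 or 4, and to 1 without PC14Br4 lung 2 or PC14Br4 skin 1 or 2. It was 4 without KM12M cecum 3 and 75 without PC14Br4 lung 1. On arrays scaled to the 75th percentile 24 passed, 8 of them higher, and MMP10 and MMP7, at 0.63 and 0.35 log2, had an adjusted p = 0.133 and 0.083. The deposited normalized values and a stricter filter each gave 0.

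Within the lines, the same contrast of brain with skin gave different numbers of probes. In KM12M, SNAP25 rose by 7.14 ± 0.46 log2 (SE, 4 and 4 tumours), EEF1A2, an elongation factor of neurons and muscle, by 6.58 log2, GPM6B, a proteolipid of neurons and glia, by 6.58 log2 and SNAP91 by 6.45 log2. The raw intensity of SNAP25 in KM12M skin was 94.1 to 103.2, where the array medians were 90.8 to 92.3. The background thus sets the size of its rise. The largest falls were in KRT19 (-2.25 log2), IFI27, an interferon-induced gene (-2.16 log2), and the epithelial genes MUC17 (-2.06 log2) and CEACAM6 (-2.01 log2). Here 732 probes passed, 302 higher and 430 lower. Before normalization the 230 probes at least 2-fold higher differed by a median of 1.48 log2, with 99.1% higher in brain. The 120 probes at least 2-fold lower differed by a median of -1.26 log2. The human signal of KM12M brain 1 and KM12M brain 2 was 99.0% and 100.3% of skin and that of KM12M brain 3 and 4 was 19.97% and 12.9%. Without KM12M brain 1 the count was 3876, without brain 2 it was 3925, without brain 3 it was 234 and without brain 4 it was 173. Without KM12M skin 1, 2, 3 or 4 it was 383, 387, 324 or 470. Fitted on these 8 arrays alone, 0 passed in limma. Arrays scaled to the 75th percentile gave 953, of which 27.5% were higher, against 41.3%.

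In MDA-MB231Br3, CAMKV rose by 7.95 ± 0.54 log2 (SE, 5 and 4 tumours), BSN by 7.66 log2, RTN1 by 7.62 log2 and FFAR4 by 7.51 log2. ADAMTS6, a secreted metalloproteinase, was at -3.48 ± 0.26 log2, MX1 at -3.44 log2, and the heat shock genes HSPA1B and HSPA1A at -3.26 and -3.23 log2. Of 10850 passing probes, 4203 were higher and 6647 lower. Before normalization the 3017 probes at least 2-fold higher differed by a median of -0.0072 log2, with 48.7% higher in brain. The 3224 probes at least 2-fold lower differed by a median of -2.63 log2. After scaling to the 75th percentile 35651 passed, 72.5% of them higher against 38.7%, with the median of all probes at 0.44 log2 against 0.045 log2. The count was 6000 without MDA-MB231Br3 brain 3 and 5605 without MDA-MB231Br3 brain 5.

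In PC14Br4, PHACTR1, an actin regulator of neurons, rose by 6.81 ± 0.91 log2 (SE, 3 and 4 tumours), FFAR4 by 6.76 log2, SNAP91 by 6.64 log2 and CAMKV by 6.60 log2. Lower were CD44 at -4.77 ± 1.12 log2, SRPX at -4.21 log2, HAUS2 at -4.10 log2 and the pseudogene HSD17B7P2 at -4.07 log2. Of 13168 passing probes, 6163 were higher and 7005 lower. Before normalization the 4344 probes at least 2-fold higher differed by a median of 0.164 log2, with 79.6% higher in brain. The 4818 probes at least 2-fold lower differed by a median of -2.57 log2. Scaled to the 75th percentile, 32823 passed, 72.2% of them higher against 46.8%, with the median of all probes at 0.35 log2 against 0.054 log2. Without PC14Br4 brain 1 the count was 948, without PC14Br4 brain 2 it was 1461, and fitted on these 7 arrays alone it was 0.

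In A375SM, SNAP91 rose by 8.32 ± 0.45 log2 (SE, 5 and 5 tumours), SNAP25 by 8.26 log2, FFAR4 by 7.85 log2 and GAD1 by 7.76 log2. The raw intensity of GAD1 in A375SM skin 2, 3 and 5 was 75.2, 79.5 and 70.8, below the array medians of 81.8, 84.1 and 83.5. It was 222.1 and 153.9 in A375SM skin 1 and 4. Background thus bears on the size of this rise. Lower were CXCL8 at -6.39 ± 0.66 log2, HAPLN1, a link protein of the hyaluronan matrix, at -6.19 log2, IFITM3, an interferon-induced antiviral gene, at -5.59 log2, and CTSL, a lysosomal protease, at -5.55 log2 with its other probe at 0.060 log2. Of 21664 passing probes, 11618 were higher and 10046 lower. Before normalization the 6011 probes at least 2-fold higher differed by a median of -0.0069 log2, with 47.5% higher in brain. The 6862 probes at least 2-fold lower differed by a median of -3.33 log2. With scaling to the 75th percentile 36766 passed, 73.1% of them higher against 53.6%, with the median of all probes at 0.53 log2 against 0.088 log2. Every A375SM brain array had 14.3% or less of the human signal of skin, so this contrast could not be fitted without the arrays poor in human signal.

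The brain minus skin difference itself differed between the lines for 4455 probes by limma's F test. The 6 genes with the smallest adjusted p were genes that A375SM expressed in skin. HAPLN1 was at -6.19 log2 in A375SM and at -0.014 to 0.028 log2 in the other lines (adjusted p = 5.72e-24). Its raw intensity was 8188 ± 1767 (SD, n = 5) in A375SM skin and 68.7 ± 7.21 (SD, n = 5) in A375SM brain, where the array medians were 71.3 to 78.4. The background thus sets the size of this fall, and its SE does not give the precision of a change in expression. CDH19, a cadherin of the Schwann cell lineage, was at -4.08 log2 in A375SM and at -0.26 to -0.059 log2 elsewhere (adjusted p = 3.14e-24). LPL, ADAMTS4, TNFAIP6 and S100A1 were at -4.14, -3.23, -3.94 and -4.27 log2 in A375SM, and in the other lines between -0.21 and 0.13 log2. CDH19 and these 4 had mean raw intensities of 69.1 to 74.8 in A375SM brain, within background as well. The count was 7386 without KM12M brain 4, 9625 without PC14Br4 brain 3 and 19509 with scaling to the 75th percentile.

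On the mouse array, most mitochondrial genome probes were higher in brain tumour samples than in skin tumour samples. Of 11, 10 rose and 1 fell, with the ND4L probe, for a subunit of respiratory complex I, at 2.41 log2, the ND5 probe at 2.24 log2, the ND2 probe at 2.17 log2 and the ND6 probe at -0.69 log2 (class adjusted p = 0.00121, adjusted p = 0.309 with an estimated correlation). Of 216 measured immunoglobulin segment probes, which mark B cells and plasma cells, 109 fell and 3 rose (adjusted p = 0.00481, adjusted p = 0.485 with an estimated correlation). Of 28 T cell receptor segment probes, 21 fell and 1 rose (adjusted p = 0.00907, adjusted p = 0.309 with an estimated correlation). Probes of other kinds fell as well: 20 of 25 bacterial, plant or reporter probes fell and 1 rose (adjusted p = 0.0134), and of 148 reverse complement probes 101 fell and 19 rose (adjusted p = 0.00907). With an estimated correlation both had an adjusted p = 0.309. The medians were -0.14 log2 for immunoglobulin, -0.22 log2 for T cell receptor, -0.17 log2 for bacterial, plant or reporter and -0.14 log2 for reverse complement probes. The immunoglobulin fall was thus no larger than that of these other kinds, and does not show fewer B cells in brain tumours. In all, 28497 of 37352 probes passed (17 brain and 17 skin tumours), 12113 higher and 16384 lower, and at least 2-fold 3709 were higher and 3422 lower. After scaling to the 75th percentile the median difference of all probes was -0.65 log2, against -0.079 log2, and 28.6% of 34881 passing probes were higher, against 42.5%. Mouse signal in skin tumours of KM12M, MDA-MB231Br3, PC14Br4 and A375SM was 15.2%, 18.2%, 32.1% and 25.6% of that of normal brain. In their brain tumours it was 74.9%, 118%, 97.2% and 117%. The counts and class shifts were not tested apart from this difference in mouse signal.

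Tumour-bearing brains differed from normal brain at fewer probes. Among the named classes, the mitochondrial ND3 probe was 1.02 log2 higher in tumour-bearing brain (adjusted p = 0.0229), 0 of 216 immunoglobulin and 0 of 28 T cell receptor segment probes passed in limma, and 1 reverse complement probe fell. The 3 normal brains and the 17 tumour-bearing brains gave 1165 passing probes, 558 higher and 607 lower, and 4629 with an unadjusted p under 0.05. At least 2-fold, 143 probes were higher and 114 lower. The count was 534 without normal brain 1, 568 without normal brain 2 and 655 without normal brain 3, and with scaling to the 75th percentile 34.5% of 2067 passing probes were higher, against 47.9%. Between the 4 groups of tumour-bearing brain, 3300 probes differed by the F test, among them 4 immunoglobulin and 1 mitochondrial probe. That count was 1927 without KM12M brain 1, 1853 without KM12M brain 2, and 998 without the 3 tumours poor in mouse signal. Raw medians on the mouse array were 112 to 117 in normal brain, 116 to 132 in KM12M brain and 63.4 to 102 in the brains of the other lines. The differences from normal brain and between the lines thus cannot be told apart from differences between sets of arrays.

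Cecum and skin tumours of KM12M differed in immunoglobulin segment probes on the mouse array. Of 216, 106 rose in cecum and 20 fell (adjusted p = 3.27e-17, adjusted p = 0.128 with an estimated correlation), with a kappa constant probe at 4.34 ± 1.13 log2 (SE, 3 and 4 tumours, adjusted p = 0.00344) and a kappa variable segment probe at 3.90 ± 0.54 log2 (adjusted p = 5.02e-07). Of 11 mitochondrial probes, 7 rose (adjusted p = 0.00199, adjusted p = 0.309 with an estimated correlation), and 7 of 28 T cell receptor segment probes fell (adjusted p = 0.0131, adjusted p = 0.309 with an estimated correlation). Of the reverse complement probes 4 rose and 26 fell (adjusted p = 0.0233), and of the bacterial, plant or reporter probes 1 rose and 9 fell (adjusted p = 0.0328), both with an adjusted p = 0.392 with an estimated correlation. In all, 9420 probes passed, 4022 higher and 5398 lower. Mouse signal was 33.2% of that of normal brain in cecum and 15.2% in skin, and the calls were not tested apart from this difference. Scaled to the 75th percentile, 2762 passed, 99.6% of them higher against 42.7%, with the median of all probes at -0.10 log2 against -0.045 log2, and without KM12M cecum 3 the count was 4666.

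Fat pad tumours of MDA-MB231Br3 differed from skin tumours at 60 mouse probes, 48 higher and 12 lower, with 2746 at an unadjusted p under 0.05, and 0 immunoglobulin, T cell receptor or mitochondrial probes passed. With scaling to the 75th percentile 6 passed, 100% of them higher against 80%. The count was 26 without fat pad 3 and 111 without fat pad 4. Lung tumours of PC14Br4 differed from skin tumours at 3425 mouse probes, 2184 higher and 1241 lower, among them 5 immunoglobulin probes higher and 4 lower. After scaling to the 75th percentile 22489 passed and 19% were higher, against 63.8%, with the median of all probes at -0.38 log2 against -0.017 log2. The count was 5798 without PC14Br4 lung 1, 1768 without PC14Br4 lung 2 and 2177 without PC14Br4 lung 3. Mouse signal was 25.3% of that of normal brain in fat pad and 18.2% in skin of MDA-MB231Br3. In PC14Br4 it was 72.7% in lung and 32.1% in skin. The calls were not tested apart from these differences.

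Mixtures of PC14 cells with normal brain differed from normal brain at few mouse probes in the main fit. The count was far higher with only the groups compared in the fit and with array weights, as given under the processing alternatives. The PC_BRM mixtures, which had 49.2% of the mouse signal of normal brain, were higher than normal brain at 4 probes and lower at 0 in limma, with 1487 at an unadjusted p under 0.05. Of the immunoglobulin, T cell receptor and mitochondrial probes, 0 passed. As classes, immunoglobulin (median 0.055 log2, adjusted p = 0.0061), T cell receptor (0.084 log2, adjusted p = 0.0341), reverse complement (0.043 log2, adjusted p = 0.00199) and bacterial, plant or reporter probes (0.064 log2, adjusted p = 0.00626) were called higher, and none of them was called with an estimated correlation, where the adjusted p = 0.485 for the first and 0.309 for the others. Scaled to the 75th percentile, 29 probes passed, with the median of all probes at 0.28 log2 against -0.0093 log2, and leaving out any single normal brain or mixture left 0 to 2.

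The level of neuron genes on the human array was higher in brain samples with more mouse signal for their human signal. Over the 17 brain tumours, centred within line, the mean log2 of the 43 neuron genes on the human array correlated with the log2 ratio of mouse to human signal (r = 0.979, permutation p = 8e-04, adjusted p = 0.0032; rho = 0.929, permutation p = 0.00204, adjusted p = 0.00816). Without the 2 tumours farthest from the median, r was 0.974. The human signal in the ratio and the neuron level both came from the human array, so part of this relation may be built in. With the level of the 664 brain probes on the mouse array, r was 0.882 (permutation p = 0.00974, adjusted p = 0.0147) and rho 0.841 (permutation p = 0.00971, adjusted p = 0.0194), and r was 0.81 without the 2 farthest. Of the 4 relations computed, the other two left out KM12M brain 1, KM12M brain 2 and PC14Br4 brain 3, the tumours with the least mouse signal. The ratio then gave r = 0.94 (permutation p = 0.011, adjusted p = 0.0147) and rho = 0.802 (permutation p = 0.0326, adjusted p = 0.0435), with r = 0.851 without the 2 farthest. The brain probes gave r = 0.399 (permutation p = 0.361, adjusted p = 0.361) and rho = 0.231 (permutation p = 0.495, adjusted p = 0.495), so the second relation rested on those 3 tumours.

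**Figure D2:**
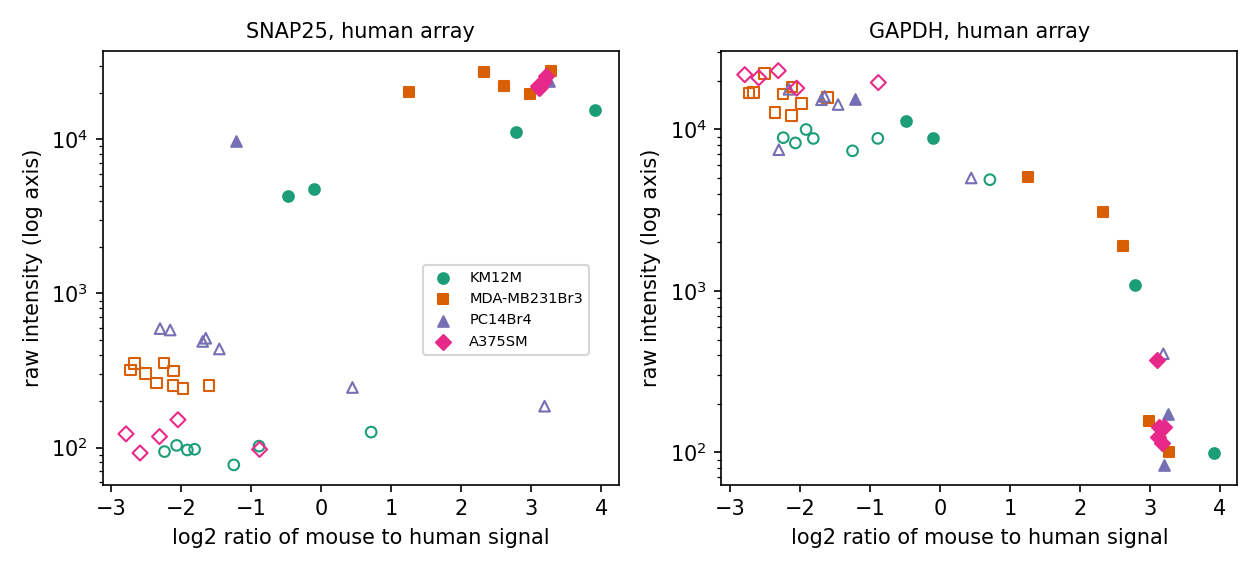
Raw intensity on the human array (log axis) of SNAP25 on the left and GAPDH on the right against the log2 ratio of mouse to human signal, 1 point per tumour, filled for brain and open for the other sites, with colour and shape giving the line. Over the brain tumours the ratio runs from -1.22 to 3.92; the filled SNAP25 points all lie above the open ones, and A375SM brain averages 23150 for SNAP25 and 179.9 for GAPDH.

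Human probes of some neuron genes also gave signal where normal mouse brain was mixed in. On the single human array of PC14 cells mixed with normal mouse brain, RTN1 was 5.35 log2, SNAP25 5.22 log2, MBP 4.53 log2 and GAD1 3.07 log2 above the mean of PC14Br4 skin, and GAPDH was at -0.27 log2. Other neuron list genes went the other way, with ENO2 at -2.73 log2, VAMP2 at -0.46 log2 and NRGN at -0.345 log2. The median of the neuron list was 0.12 log2, at percentile 99.2 of random lists, and that of the oligodendrocyte and myelin list 0.25 log2, at percentile 99.9. The GABA and glutamate handling list, which holds GAD1, lay at -0.17 log2 (percentile 9.76). The cell cycle list lay at 0.28 log2 (percentile 99.7), the lymphocyte list at 0.18 log2 (percentile 98.2) and the lung epithelium list at 0.14 log2 (percentile 96.3). The hypoxia list lay at -0.75 log2 (percentile 0), the interferon response list at -0.54 log2 (percentile 0.01), with ISG15 at -2.41 log2, and the cholesterol synthesis list at -0.47 log2 (percentile 0.3). There was no replicate, so no test was run.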

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

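The tests on correlations over brain tumours, on the 3 tumours of low mouse signal, on the 22 neuron genes before normalization and on the mouse array without 3 tumours were chosen after the result was seen. The test of the 3958 probes before normalization and that of the PC_BRM mixtures were written beforehand.

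A single array stood apart from its group in 2 of 48 combinations of group and measure, where chance gives about 1 in 20. The raw median of KM12M skin 4 on the human array was 90.8, against 92 to 92.3 in the other skin tumours of the line. The raw median of A375SM skin 3 on the mouse array was 73.6, against 65.6 to 67. The brain minus skin difference differed between the lines at 4455 human probes, and the tumour-bearing brains of the lines differed at 3300 mouse probes, both by limma's F test. The single human array of PC14 cells mixed with mouse brain had a SNAP25 raw intensity of 6261, against 436.5 to 591.7 in PC14Br4 skin. The BR_PCM mixture, which entered no comparison, had a mouse signal of 187, against 57.4 to 141 in PC14Br4 skin.

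Higher in brain than in skin tumours by at least 2-fold were 3958 human probes, and 22 of the 43 neuron list genes were called higher while 13 were lower. Over the 22 neuron list genes that rose, the raw level in the 17 brain tumours rose with the ratio of mouse to human signal (r = 0.929, permutation p = 0.00454). It fell with human signal (r = -0.91, permutation p = 0.00685). These genes were picked by their rise in brain samples, most of which held little human signal, and this favours such signs. For these genes the test thus cannot decide between mouse brain RNA binding the human probes and expression by the tumour cells, alone or in addition. The 285 probes higher by 1 log2 or more before normalization gave r = 0.939 and r = -0.898, but picking probes by their raw rise favours these signs, so here the sources cannot be told apart. Over all 3958 probes r was -0.518 with the ratio and 0.52 with human signal, but 0.543 and -0.493 once the array median was subtracted, a condition added after these values were seen because that median itself went with the ratio (r = -0.845), so the sources cannot be told apart for the whole set. Over the 3958 probes the median difference was 1.72 log2 after normalization and 0.018 log2 before it, where 285 rose by 1 log2 or more. The 2-fold size of most of these rises thus came with background correction and normalization. Whether their direction did stays open, with 57% higher before normalization. Normalization stays open too for the 22 genes, with a raw median difference of 0.68 log2 and 77.3% higher before normalization.

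Lower in brain by at least 2-fold were 5546 human probes, at a median of -1.67 log2. Over the 3 brain tumours of low mouse signal (KM12M brain 1, KM12M brain 2 and PC14Br4 brain 3), their median difference from skin was -0.030 log2. It was -1.38 log2 over all brain tumours of these lines. Of the probes, 0.288% were lower by 1 log2 or more, against 80%. The 3 tumours were chosen by the mouse array, but they also had 99.0%, 100.3% and 95.7% of the human signal of skin. The choice was thus not independent of the probes tested, and it favoured a small difference. The values show that most of these probes kept their level in KM12M and PC14Br4 samples that kept human signal. They cannot by themselves tell less human RNA in the other brain samples from lower expression in the tumour cells. Lower expression only where more mouse tissue lies around the tumour cells stays open, single genes may still differ, and for MDA-MB231Br3 and A375SM, with no such tumour, the test says nothing. Why the human signal was lower in most brain samples was not tested.

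Higher in tumour-bearing than in normal brain by at least 2-fold were 143 mouse probes, at a median of 1.29 log2. Between the PC_BRM mixtures and normal brain their median was -0.0899 log2 and their upper quartile 0.0055 log2, which argues against binding of human RNA, as far as PC14 cells stand for the 4 lines. Without the 3 tumours of low mouse signal the median was 1.39 log2, which argues against these tumours as its source. A response of the host brain to the tumour is the biological explanation that the design names, and it may account for the rise. It was not tested apart from other differences between the animals or between the arrays. Raw medians were 112 to 117 in normal brain and 116 to 132 in KM12M brain, but 63.4 to 102 in the brains of the other lines. A difference between sets of arrays thus cannot be told apart from a response of the host.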

How the results depend on the processing

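Left out one array at a time, counts of passing probes ranged from 24674 to 27949 for brain against skin over 4 lines, 7956 to 19067 for brain against the third site, 0 to 75 for the third site against skin, 3677 to 9625 for the difference between lines, 173 to 3925 for KM12M, 5605 to 15154 for MDA-MB231Br3, 948 to 18526 for PC14Br4 and 20280 to 21711 for A375SM on the human array. On the mouse array they ranged from 27776 to 28678 for brain against skin, 534 to 1272 for tumour-bearing against normal brain, 1853 to 3797 between the brains of the lines, 4666 to 10628 for KM12M cecum, 26 to 111 for MDA-MB231Br3 fat pad, 1768 to 5798 for PC14Br4 lung and 0 to 2 for the PC_BRM mixtures. The third site against skin within a line on the human array, a comparison chosen after seeing the data, ranged from 16 to 56 for KM12M cecum, 0 to 0 for MDA-MB231Br3 fat pad and 0 to 1 for PC14Br4 lung. The correlation of neuron genes with brain probes ranged from 0.851 to 0.9, and missed the threshold without PC14Br4 brain 3 (0.851).

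Arrays that moved a count by over 1.5 times were PC14Br4 brain 1 (7956) and PC14Br4 lung 1 (8943) for brain against the third site; KM12M brain 4 (7386) and PC14Br4 brain 3 (9625) for the difference between lines; and for the human KM12M contrast brain 1 (3876), brain 2 (3925), brain 3 (234), brain 4 (173), skin 1 (383), skin 2 (387), skin 3 (324) and skin 4 (470). For MDA-MB231Br3 they were brain 3 (6000) and brain 5 (5605), and for PC14Br4 brain 1 (948) and brain 2 (1461). The third site against skin fell to 0 without KM12M skin 1, 3 or 4, KM12M cecum 1, MDA-MB231Br3 fat pad 2, 3 or 5, MDA-MB231Br3 skin 2, 3 or 4, PC14Br4 lung 3 or PC14Br4 skin 3 or 4, and gave 1 without PC14Br4 lung 2 or PC14Br4 skin 1 or 2, 4 without KM12M cecum 3 and 75 without PC14Br4 lung 1. On the mouse array they were normal brain 1 (534), 2 (568) and 3 (655), then KM12M brain 1 (1927) and 2 (1853), KM12M cecum 3 (4666), fat pad 3 (26) and 4 (111), and PC14Br4 lung 1 (5798), 2 (1768) and 3 (2177). For the PC_BRM mixtures they were normal brain 1 (0), 2 (1) and 3 (0) and mixtures 1 (2), 2 (0) and 3 (0). For human KM12M cecum they were skin 2 (16), skin 3 (18), cecum 1 (24) and cecum 3 (56), and for human PC14Br4 lung, lung 1 (1).

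Scaling to the 75th percentile gave 33875 for brain against the third site, 24 for the third site against skin, 19509 for the difference between lines, 35651 for MDA-MB231Br3, 32823 for PC14Br4, 36766 for A375SM and 2 for KM12M cecum on the human array. On the mouse array it gave 2067 for tumour-bearing against normal brain, 22484 between the brains of the lines, 2762 for KM12M cecum, 6 for fat pad, 22489 for lung and 29 for the PC_BRM mixtures. With only the groups compared in the fit, so with fewer samples behind the spread, the counts were 1153 for brain against the third site, 10 for the third site against skin, 0 for KM12M, 6287 for MDA-MB231Br3 and 0 for PC14Br4; on the mouse array 2845 for tumour-bearing against normal brain, 9374 between the brains of the lines, 1009 for KM12M cecum, 1 for fat pad, 562 for lung and 455 for the mixtures. Array weights gave 312 for brain against the third site, 89 for the third site against skin, 22626 for the difference between lines and 20272 for PC14Br4; on the mouse array 6663 for tumour-bearing against normal brain, 11035 between the brains of the lines, 101 for fat pad, 6672 for lung and 676 for the mixtures; their fit stopped before it converged in some cases. A stricter filter, which tests fewer probes, gave 0 for the third site against skin, 17775 for mouse brain against skin, 1876 between the brains of the lines and 15 for the mixtures, and no filter 2 for the mixtures. The deposited normalized values gave 0 for the third site against skin. Leaving out probes that rose on the mixture gave 453 for KM12M. Except where fewer samples or probes were used, the cause was not tested. Counts stayed within 1.5 times of the reported one for brain against skin over 4 lines in every alternative but leaving out the arrays poor in human signal, for A375SM in every one that could be fitted but scaling, and for mouse brain against skin in every one but the stricter filter.

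With the replicate number as a block, the third site against skin gave 0, MDA-MB231Br3 6795, tumour-bearing against normal brain 196, the brains of the lines 247, the mixtures 0 and human KM12M cecum 60. Over 74 pairs of equally numbered arrays from 2 sites of a line, their correlations ran from -0.682 to 0.78 with a median of 0.024, and 17 were over 0.1. In 1 of 20 sets of such pairs, KM12M brain and cecum on the human array, each of the 3 was over 0.1 (0.165 to 0.175), but 0 of these 3 were the best match of both their arrays. In 0 of the 20 sets did each array correlate best with its own number, so pairing was not taken as shown; brain against the third site gave 11287 with the block.

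Alternatives chosen after seeing the data used fewer samples. Without the arrays poor in human signal the counts were 2928 for brain against skin, 1340 for brain against the third site, 249 for the third site against skin, 2174 for the difference between lines, 475 for KM12M, 4095 for MDA-MB231Br3 and 303 for PC14Br4, and A375SM could not be fitted. Without PC14Br4 lung 2 and PC14Br4 brain 3 the difference between lines gave 12407, and without the tumours poor in mouse signal the brains of the lines gave 998. Without KM12M brain 1 and 2 and PC14Br4 brain 3 the correlation was 0.399. The chip as a block was not run, as no chip numbers were read.

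Of 305 pairs of a named gene and a contrast, 20 turned sign with scaling to the 75th percentile and 1 with array weights. Without the arrays poor in human signal 36 of 297 pairs turned. Another probe of the gene had the opposite sign in 25 of 77 cases. Under the other alternatives 0 pairs turned. Keeping their direction, 24 pairs lost their call with scaling, 107 with array weights and 113 with only the groups compared. It was 176 without the arrays poor in human signal, 15 with the block and 40 without some single array. Among the genes in the text, scaling turned NDUFV1 (-0.82 log2). Leaving out the arrays poor in human signal turned OLIG2 (0.057), GAPDH (0.051), NDUFV1 (-0.18) and COX6C (0.047) for brain against skin and EBP (0.028) for brain against the third site. Other probes gave FFAR4 -0.0012, MBP -0.68, OAS1 -0.66 and -0.026 and SOD2 -0.056 for brain against skin, MBP -1.34 for brain against the third site, and CTSL 0.060 in A375SM. Of 90 list tests, 13 lost their call with an estimated correlation, 2 lost and 20 gained one with scaling, 10 lost and 9 gained one without the arrays poor in human signal, 5 lost and 1 gained one without PC14Br4 lung 2 and PC14Br4 brain 3, and 0 turned direction. Low human signal over background limits the brain results on the human array.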

Other observations

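All tests within a line on the third site of growth and on tumours that kept human signal were chosen after the data were seen; the splits of the samples were planned. The genes named in this part were chosen after their values were seen. Within KM12M, 31 human probes were higher in cecum than in skin tumours. CXCL8 rose by 2.39 ± 0.17 log2 (SE, 3 and 4 tumours, adjusted p = 0.000338), CXCL1 by 2.21 ± 0.18 log2 and CCL20 by 3.12 ± 0.41 log2, all of them chemokines. LCN2, an iron-binding protein of inflamed epithelium, rose by 4.03 ± 0.39 log2, MMP10 by 3.60 ± 0.25 log2, MMP7 by 1.08 ± 0.11 log2, TFF2, a trefoil peptide of mucus, by 2.16 ± 0.29 log2, and NFKBIA, the NF-kB inhibitor that NF-kB induces, by 0.80 ± 0.12 log2. HBA1, an alpha globin, rose by 3.17 ± 0.30 log2, TPM2, a tropomyosin, by 2.64 ± 0.30 log2 and SPARCL1 by 1.84 ± 0.17 log2. The SPARCL1 probe was also 4.29 log2 above PC14Br4 skin on the mixture with mouse brain, and mouse signal was 33.2% of that of normal brain in cecum and 15.2% in skin. In all 37 probes passed, 31 higher and 6 lower, with 3635 at an unadjusted p under 0.05, but only 2 with scaling to the 75th percentile. Of the 17 NF-kB inflammation genes 5 passed and 17 were above 0 (adjusted p = 5.98e-14, adjusted p = 0.117 with an estimated correlation). Of the 18 interferon response genes 1 was above 0, at a median of -0.26 log2 (adjusted p = 0.00139, adjusted p = 0.476 with an estimated correlation). The gut epithelium and antigen presentation lists were higher (adjusted p = 0.00751 and 0.0201, adjusted p = 0.476 and 0.369 with an estimated correlation). The count was 16 without KM12M skin 2, 18 without KM12M skin 3, 24 without KM12M cecum 1 and 56 without KM12M cecum 3. In the same limma fits within a line, fat pad against skin of MDA-MB231Br3 gave 0 probes (2262 at an unadjusted p under 0.05) and lung against skin of PC14Br4 gave 0 (1794), with 16 of the 18 interferon response genes above 0 at a median of 0.28 log2 (adjusted p = 1.91e-05, adjusted p = 0.595 with an estimated correlation). The cell cycle list had 2 of 28 above 0 at a median of -0.73 log2 and cholesterol synthesis 1 of 16 at -0.86 log2 (adjusted p = 0.000169 and 0.00351, adjusted p = 0.784 for both with an estimated correlation), and NF-kB inflammation 13 of 17 (adjusted p = 0.0234, adjusted p = 0.492 with an estimated correlation). In fat pad the cell cycle, endothelium, epithelial adhesion and oxidative phosphorylation lists were higher (adjusted p = 0.0433, 0.0258, 0.0201 and 0.0201), and not called with an estimated correlation. Without PC14Br4 lung 2 it was again 0 (3129), with all 18 interferon response genes above 0 at a median of 0.72 log2 (adjusted p = 5.82e-20, adjusted p = 0.29 with an estimated correlation). Then hypoxia had 15 of 17 above 0 and the cell cycle list 3 of 28 (adjusted p = 1.62e-05 for both), antigen presentation 10 of 13 (adjusted p = 0.000437), NF-kB inflammation 15 of 17 (adjusted p = 0.00346), cholesterol synthesis 3 of 16 (adjusted p = 0.00412) and glycolysis 8 of 10 (adjusted p = 0.0259), none of them called with an estimated correlation. The cell cycle and cholesterol synthesis medians shrank to -0.25 and -0.32 log2 without lung 2. The hypoxia median was 0.41 log2 without lung 2 and -0.145 log2 with it. HERC5 and BST2, both interferon-induced, were without lung 2 at 1.16 ± 0.089 and 1.57 ± 0.13 log2 (adjusted p = 0.0827 for both).

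The tumours that kept human signal were 2 KM12M, 1 MDA-MB231Br3 and 1 PC14Br4 brain tumours with the 12 skin tumours of these lines. Between them HSPA6, a heat shock gene, fell by 1.65 ± 0.36 log2 (SE, 4 brain and 12 skin tumours, adjusted p = 0.00347), DNAJB1 by 0.99 ± 0.22 log2 and HSPA1B by 0.97 ± 0.21 log2, though in PC14Br4 they were at -0.63, -0.38 and -0.069 log2. MMP1, a collagenase, fell by 1.43 ± 0.37 log2, ANXA1 by 0.99 ± 0.16 log2 and CCN1, a matricellular protein, by 0.92 ± 0.21 log2. These were at -2.19, -1.97 and -1.51 log2 in the single PC14Br4 tumour, at -1.32, -0.27 and -1.03 log2 in the single MDA-MB231Br3 tumour and at -0.77, -0.74 and -0.22 log2 in KM12M. Among the genes whose raw intensity was at least 1 log2 lower in A375SM brain, SCNN1A, a sodium channel subunit, was 0.90 ± 0.12 log2 higher, FASN, the fatty acid synthase, 0.80 ± 0.23 log2 and FKBP5, which glucocorticoids induce, 0.68 ± 0.12 log2. The single MDA-MB231Br3 tumour gave the largest of these rises, 2.11, 1.29 and 1.45 log2, against 0.58, 0.46 and 0.24 log2 in KM12M and 0.0012, 0.66 and 0.36 log2 in PC14Br4. In all 2928 probes passed, 1756 higher and 1172 lower, and of the higher ones 950 had a higher and 806 a lower raw level in A375SM brain. The neuron list had 15 genes higher and 0 lower on these tumours.

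Other splits of the same samples were counted for each fit, drawn within lines where a contrast between sites spans lines. For tumour-bearing against normal brain, and for the tumour-bearing brains of the lines, they were drawn over all tumour-bearing and normal brains together. Chance was called excluded by a share under 0.05, and the shares were not adjusted over the fits. On the human array this held for brain against skin over 4 lines (26734 probes, 1 of 100 splits gave as many, the highest other 8918) and for A375SM (21664, 1 of 100, highest other 12671). It held for KM12M (732, 1 of 35, highest other 132) and PC14Br4 (13168, 1 of 35, highest other 12553) at the lowest share that 35 splits allow. Leaving out 1 array gave 173 to 3925 for KM12M and 948 to 18526 for PC14Br4. Fitted on its own arrays alone each of these 2 lines gave 0, so their support is limited. Chance is named in the same sense below. It can also be excluded, by their share, where other splits reached more. These were brain against the third site (14271, 3 of 100, highest other 16073) and MDA-MB231Br3 (10850, 3 of 100, highest other 15386). For the difference between lines (4455, 3 of 100, highest other 16182) the splits exchanged brain and skin within a line. They thus also removed the brain and skin difference that the lines share, and cannot decide whether this count is chance. The third site against skin (2; 4 of 100, highest other 4) stands by its share too, but on a count that fell to 0 without any of several single arrays and under other alternatives, so this gives it little support. On the mouse array chance can be excluded for brain against skin (28497, 1 of 100, highest other 16088), KM12M cecum (9420, 1 of 35, highest other 9325) and MDA-MB231Br3 fat pad (60, 3 of 100, highest other 116). For tumour-bearing against normal brain (1165, 1 of 100, highest other 710) the splits also removed the differences between lines. For the tumour-bearing brains of the lines (3300, 1 of 100, highest other 1778) they also exchanged the normal brains. They thus cannot decide whether these 2 counts are chance. Chance cannot be excluded for PC14Br4 lung (3425; 2 of 35, highest other 3455). For the PC_BRM mixtures there were too few splits for a share under 0.05 (4 probes; 5 of 10, highest other 109). For the third site within a line on the human array it can be excluded for KM12M cecum (37; 1 of 35, highest other 28). For MDA-MB231Br3 fat pad (100 of 100 splits, highest other 64) and PC14Br4 lung (35 of 35, highest other 0) the real count was 0, which any split reaches, so the splits say nothing there. Splits that called several times the real count, as for the difference between lines and the PC_BRM mixtures, may point to a structure of the samples other than their groups, which was not tested.

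The 6 relations computed over the 17 brain tumours on raw levels, centred within line, had these further values. The 22 neuron genes gave rho = 0.838 with the ratio of mouse to human signal (permutation p = 0.012, adjusted p = 0.024; adjusted p = 0.0137 for r, and r = 0.831 without the 2 farthest tumours). With human signal they gave rho = -0.855 (permutation p = 0.00947, adjusted p = 0.024; adjusted p = 0.0137 for r, and r = -0.806 without the 2 farthest). The 285 probes gave rho = 0.806 with the ratio (permutation p = 0.0251 and 0.00645 for r, adjusted p = 0.0261; adjusted p = 0.0137 for r, and r = 0.834 without the 2 farthest) and rho = -0.794 with human signal (permutation p = 0.0261 and 0.013 for r, adjusted p = 0.0261; adjusted p = 0.0195 for r, and r = -0.765 without the 2 farthest). All 3958 probes gave r = -0.518 with the ratio (permutation p = 0.027, adjusted p = 0.0324, and r = -0.383 without the 2 farthest) with rho = -0.667 (permutation p = 0.00565, adjusted p = 0.024). With human signal they gave r = 0.52 (permutation p = 0.0346, adjusted p = 0.0346, and r = 0.383 without the 2 farthest) with rho = 0.586 (permutation p = 0.023, adjusted p = 0.0261). Less the array median, the permutation p was 0.108 for 0.543 and 0.143 for -0.493.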
